A study of Mus musculus with 21 samples.

How the data were processed

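The authors deposited a GenomeStudio table per batch with the average bead intensity of each probe on each array, not normalized and without background subtraction per the file headers. Beside each intensity stands the deposited detection p-value, the share of negative control beads at least as bright. The batch A table holds 12 arrays, of which 3 match no sample and were not used, and the batch B table holds 12 arrays, all used. The 9 and 12 arrays were joined to samples by the beadchip and position that the labels state, and 0 pairs of arrays were identical. Voltage in Vpp, frequency in kHz, time in min and temperature in °C are given per the labels.

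For comparisons within a batch, each batch was processed alone with limma 3.58.1 in R 4.3.3, and tables were read with data.table (version 1.17.8). Background was removed by the normal-exponential model with its parameters inferred from the deposited detection p-values, an offset of 16 was added, arrays were quantile normalized and log2 was taken. Quantile normalization gives every array of a batch one distribution, so that a change of all transcripts together is not seen. Probes with a deposited detection p below 0.01 on at least 3 arrays of the batch were kept, 14130 in batch A and 13773 in batch B. One probe per gene was used, the one with the highest mean, which left 9675 genes in batch A and 9544 in batch B. Probe names came first from the deposited accession (29370 probes), then from the Entrez identifier (2975), the symbol (2214) or a synonym (2371), by a naming table of mouse build GRCm38.p6 that was used for names only, and no coordinates are given. For 8351 probes the name in the file was kept, among them those of 1190 tested genes in batch A and 1100 in batch B.

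Groups were compared with limma's linear model and moderated statistics, two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. The prior degrees of freedom were 2.7 in batch A and 4.5 in batch B. Effects of actuation and of heat were compared in a joint fit of 10378 genes, after the same background removal and quantile normalization over all 21 arrays together, as the difference between each treatment's change against the untreated group of its own batch, and levels were compared between batches only in 1 test of the closing section. The tests, the gene lists and the alternatives were fixed before the data were examined, except where the closing section says otherwise. Of 33 lists 30 had at least 4 measured genes and were tested with camera at a preset correlation of 0.01, adjusted over all lists and comparisons of a batch. The same test with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, and fry asks whether a list moves on balance one way.

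Genes are named by a fixed rule. Per comparison these are the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap. Where fewer than 4 genes pass, the 5 with the smallest p are given as values. Added to these are 12 stress genes where measured and, for each shifted list and always for the heat shock and immediate early lists, up to 4 members with the smallest p. Probes without a gene name were left out, and the text gives a selection of the genes so named. Some genes that the rule names are not reported here. Where a gene was detected on 0 of 3 arrays of a group, the bound on its fold change sets that group at the lowest detected level of each array, or at the gene's own level where higher, and no fold is given where both groups lie at background. The same bound for genes detected on 1 or 2 arrays was added after the results were seen.

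The alternatives were no background correction, an offset of 50, scaling by the median only, normalizing all 21 arrays together, no detection filter, detection on every array, all probes, array weights, a trended and robust prior, only the arrays of the 2 groups, beadchip or replicate number as a block, each beadchip alone, and leaving out each array. The deposited log2 table was another: it holds 40083 probes, centred by the authors on a median of 0 over the 21 arrays, by a method that the labels do not state. Its probes were matched through the deposited table with manufacturer identifiers, in which 1 of 45281 rows has batch A and batch B values of the same probe, so that only its batch B columns were used. The resulting correlations with log2 intensities were 0.961 to 0.995 for batch B arrays and 0.718 to 0.976 for batch A arrays, against -0.031 to 0.011 when matched through the batch A columns.

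In a self-test, 200 changed genes were added to arrays simulated with each gene's pooled spread in its batch. With the spread of batch A 74% were found at a change of 1 log2 and 98% at 2, and 14 of 9455 unchanged genes were called. With that of batch B these were 93%, 99% and 6 of 9324. For differences between effects 96.5% of 200 were found, and 0 of 200 changed alike in both batches were called. Unequal spread (median SD 0.263 at 18 kHz, 0.124 in untreated batch A) was not simulated, so that these rates may not hold there.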

Results

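Transcript levels were measured on Illumina BeadChip arrays in Ba/F3 cells, a mouse pro-B cell line that depends on interleukin 3. On a digital microfluidic device, voltages on electrodes under an insulating layer move droplets, and cells suspended in the droplets are exposed to the field and to any warming. Cells were actuated on such a device for 15 min at 400 Vpp and 1 or 18 kHz, or heated for 15 min at 42, 47 or 52 °C. The 21 arrays fell into 7 groups of 3. Batch A held 9 arrays (untreated, 1 kHz and 18 kHz) and batch B held 12 (untreated, 42 °C, 47 °C and 52 °C), so that each batch had its own untreated group. Each array read 45281 probes, of which 9420 to 14355 per array were detected in batch A and 12004 to 13234 in batch B. The 95th percentile of the bead intensity ran from 277.4 to 1857.1 in batch A and from 846 to 1563.7 in batch B. The 18 kHz arrays were the dimmest of batch A, with 95th percentiles of 732.7, 277.4 and 1110.7 against 1482.4 to 1524.2 in its untreated arrays. Within-group correlations of the log2 intensities were 0.957 to 0.970 at 18 kHz, 0.972 to 0.991 at 52 °C and 0.982 to 0.996 in the other 5 groups. Each batch was read on a pair of beadchips, and the number of arrays limits the precision of all values. Levels are log2 normalized intensities as mean ± SD (n = 3 arrays per group), and changes are differences of the means. A change was called at an adjusted p below 0.05 from limma. For the largest changes named here, the 3 arrays of one group lay entirely above or below the 3 of the other. The p-values measure the spread between these samples, since no label says that the replicates were separate cultures, and no label states the time from treatment to lysis. A gene detected on 0 of 3 arrays of a group is given only as a lower bound on its fold change, and so are genes detected on 1 of 3 where they changed, with their undetected arrays at the lowest detected level.

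The comparison of 18 kHz with untreated cells asked which transcripts differed after actuation at the higher frequency. Of 22 measured genes of the immediate early response, which growth factor and stress signals switch on within minutes, 10 were lower at 18 kHz, and 12, among them Jun (-0.59, adjusted p = 0.277) and Egr1 (-0.54, adjusted p = 0.254), did not pass. Fos (probe 510368), which encodes a subunit of the AP-1 transcription factor, fell 75.8-fold from 12.19 ± 0.38 to 5.95 ± 0.51 and was detected on 2 of 3 arrays at 18 kHz (at least 56.0-fold with the other at the lowest detected level, adjusted p = 4.21e-05). Its relative Fosb (probe 6420520) stood at 8.67 ± 0.39 in untreated cells and fell at least 6.34-fold, to 0 of 3 arrays with detection (adjusted p = 7.97e-05). Dusp1 (probe 4200100), a phosphatase that switches off MAP kinases, fell 9.67-fold from 11.17 ± 0.49 to 7.90 ± 0.34 (adjusted p = 0.000653). The related phosphatase Dusp2 fell at least 6.34-fold and was detected on 1 of 3 arrays at 18 kHz. Egr2, a zinc finger transcription factor of the same response, fell at least 13.3-fold with detection on 1 of 3 arrays (adjusted p = 0.0029). Mir17hg, the host transcript of a microRNA cluster that promotes growth, fell at least 7.69-fold, also with detection on 1 of 3 (adjusted p = 0.000571). Falls of 2.00 to 3.17 log2 were found for Csrnp1, a transcription factor, Zfp36, which promotes decay of cytokine mRNAs, the cytokine Osm, Nfkbiz, a nuclear regulator of NF-kB, and Ier3, a survival factor. Each of these falls passed the test whichever single array was left out.

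The largest rises at 18 kHz were smaller than the largest falls. Neat1 (probe 1690497), the long noncoding RNA that organizes nuclear paraspeckles, rose 3.88-fold to 10.96 ± 0.38 (adjusted p = 0.00246). Arhgef2 (probe 7400300), a protein bound to microtubules, rose 5.31-fold from 6.47 ± 0.48 to 8.88 ± 0.28 (adjusted p = 0.0029), although 1 of its 3 other probes changed in the opposite direction. Both rises passed whichever single array was left out, and under median scaling Neat1 did not pass. Clec2d (probe 7570181), a lectin-like ligand of a natural killer cell receptor, rose 3.43-fold to 10.11 ± 0.11 (adjusted p = 0.00948, and 0.0659 without untreated replicate 3). Prrc2c, whose product takes part in stress granule formation, rose by 3.51 log2 to 11.40 ± 1.49 (adjusted p = 0.0294), with 1 of 5 other probes called the same way. Its call was lost without untreated replicate 1, 2 or 3 or 18 kHz replicate 1, with an adjusted p of up to 0.139. Heat shock genes did not pass: Dnajb1 (probe 4540020), an HSP40 co-chaperone, changed by -0.44 (adjusted p = 0.0863), Hsph1 (probe 3290270), an HSP110 chaperone, by 0.33 (adjusted p = 0.148) and Hspa8, the constitutive HSC70, by -0.07 (adjusted p = 0.603). The inducible HSP70 genes Hspa1a and Hspa1b were detected on 0 of 9 arrays of batch A.

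**Figure D1:**
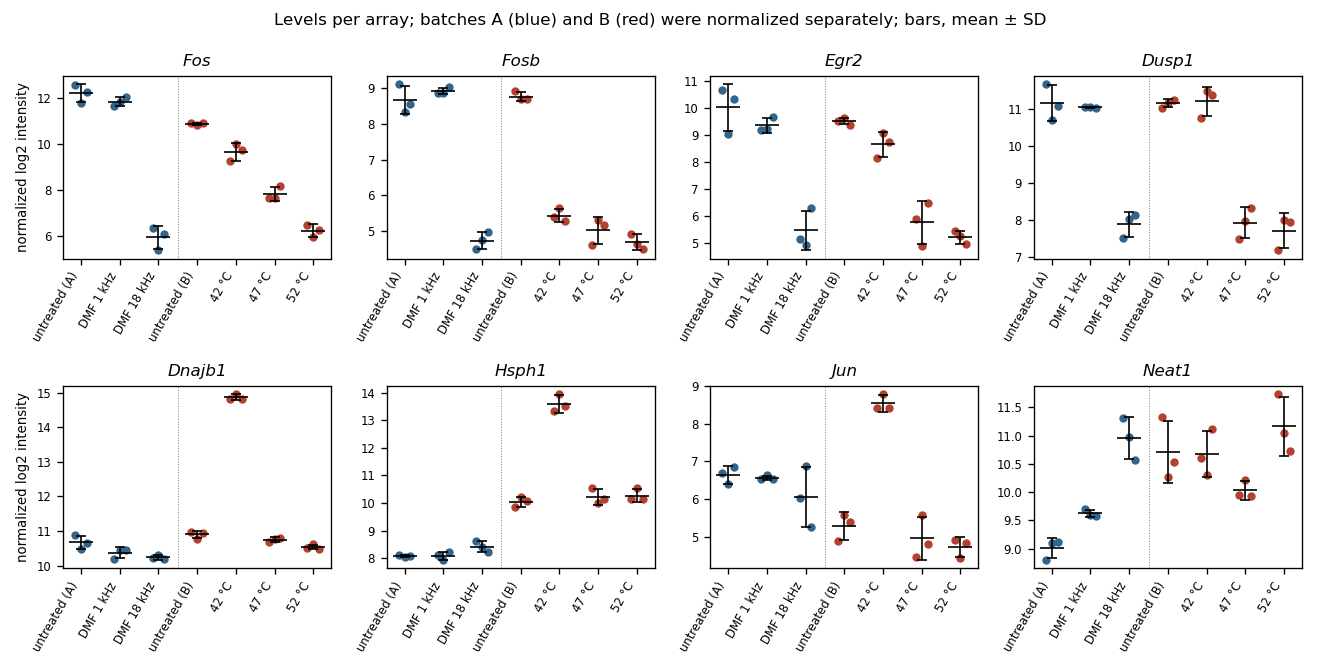
Levels (log2 normalized intensity) of 8 genes on each array, with points for arrays and mean ± SD (n = 3) for groups; batches were normalized separately. Fos ran from 12.19 ± 0.38 in untreated cells of batch A to 5.95 ± 0.51 at 18 kHz, and Dnajb1 from 10.90 ± 0.10 in untreated cells of batch B to 14.87 ± 0.08 at 42 °C.

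Of the lists of genes fixed before the data were examined, 6 shifted at 18 kHz, all downward, and 0 held with an estimated correlation. The immediate early list had 22 measured genes, of which 0 rose, 10 fell and 12 did not pass (13 fell adjusted over the list alone). Its median change was -0.82 (-0.58 with bounds; adjusted p = 1.53e-09, and adjusted p = 0.316 with an estimated correlation), and -1.04 on the beadchip that held both groups. Among 12 NF-kB target genes 2 fell, including Nfkbiz and the chemokine gene Ccl3 (at least 2.86-fold, adjusted p = 0.00948), and 6 fell adjusted over the list alone. Their median was -0.48 (adjusted p = 0.00335, and 0.0614 without 18 kHz replicate 3; adjusted p = 0.316 with an estimated correlation). Of 19 splicing regulators, 3 fell (7 adjusted over the list alone), namely Srsf7 (-0.97), Srsf6 (-1.03) and Tra2b (-0.94), each of which was lost without any of the untreated arrays or without 18 kHz replicate 1, and Srsf6 and Tra2b also without 18 kHz replicate 2, with adjusted p up to 0.167. Without both of these 18 kHz arrays none of the 3 passed (-0.66, -0.67 and -0.52, adjusted p = 0.0765, 0.191 and 0.205). The splicing median was -0.37 (adjusted p = 0.019; adjusted p = 0.68 with an estimated correlation). Of 19 unfolded protein response genes, 2 fell (2 adjusted over the list alone): Dnajb9, a co-chaperone of the endoplasmic reticulum (-0.96, adjusted p = 0.00854, and up to 0.06 without untreated replicate 1 or 3), and Calr, its calcium-binding chaperone (-0.80, adjusted p up to 0.0937 without untreated replicate 1, 2 or 3 or 18 kHz replicate 1). Their list's median was -0.30 (-0.28 with bounds; adjusted p = 0.0294; adjusted p = 0.68 with an estimated correlation), with adjusted p of 0.0543 and 0.056 without untreated replicates 1 and 3 and 0.137 and 0.0722 without 18 kHz replicates 2 and 3. Of 20 cholesterol genes 1 fell (6 adjusted over the list alone). The cholesterol median was -0.34 (adjusted p = 0.0294, 0.116 without untreated replicate 3 and 0.104 without 18 kHz replicate 3; adjusted p = 0.68 with an estimated correlation). Of 24 genes of the G1/S transition 1 fell (6 adjusted over the list alone), the cyclin gene Ccne2, which went from 2 of 3 arrays with detection to 0 of 3 (adjusted p = 0.00854, and 0.0601 without untreated replicate 3). Its list's median was -0.21 (-0.18 with bounds; adjusted p = 0.0278, 0.0543 without untreated replicate 1 and 0.146 without 18 kHz replicate 3; adjusted p = 0.316 with an estimated correlation). With beadchip as a block these 6 medians were -0.89, -0.53, -0.36, -0.27, -0.32 and -0.19 in the order given here, and within the shared beadchip -1.04, -0.54, -0.36, -0.28, -0.29 and -0.19. The 20 measured heat shock genes had 0 called and a median of -0.06 (adjusted p = 0.641), with -0.18 within the shared beadchip.

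In all, 246 of 9675 genes changed at 18 kHz, 129 higher and 117 lower, and 225 of them by at least 1.5-fold. At an unadjusted p below 0.05 there were 2702 genes, and 29.6% of genes had groups that did not overlap, against 10% by chance. A fit with beadchip as a block passed 144 genes, and within the beadchip that held both groups 2 passed, Fos and Fosb. The count was 38, 58 and 27 without untreated replicates 1, 2 and 3, 68 without 18 kHz replicate 1 and 2948 without 18 kHz replicate 3. Without the 2 dimmer 18 kHz arrays (replicates 1 and 2) it was 70, with the spread of the 1 array left taken from the other groups. Of the genes named here, Fos, Fosb, Egr2, Dusp1, Neat1 and Arhgef2 were among those that still passed, as did Prrc2c at 1.80 instead of 3.51 log2. Clec2d (1.66), Calr (-0.66), Ccl3 (-1.91) and Ccne2 did not (adjusted p from 0.064 for Ccl3 to 0.159 for Calr), though Clec2d and Calr moved little. Jun newly passed (adjusted p = 0.0234), at a level below detection on the array left. Median scaling, which lets arrays differ in the spread of their intensities, moved the median of all genes by -1.10 log2 and gave 7 genes higher and 4627 lower. Relative to that shift the immediate early list still lay at -0.52, and the splitting of other genes into higher and lower depended on the normalization.

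The comparison of 1 kHz with untreated cells asked the same of the lower frequency. None of the immediate early genes passed the test at 1 kHz. Fos stood at 11.82 ± 0.20 against 12.19 ± 0.38 in untreated cells (-0.38, adjusted p = 1). The heat shock genes Dnajb1 (-0.31), Hsph1 (0.00) and Hspa8 (-0.02) did not pass either, nor did Jun (-0.08), the AP-1 partner of Fos, Hmox1 (-0.08), the heme oxygenase of oxidative stress, or Ddit3 (-0.22), the transcription factor CHOP of the integrated stress response. By limma 0 of 9675 genes changed, with 173 genes at an unadjusted p below 0.05 and 12.5% of genes with groups that did not overlap. Among the smallest unadjusted p-values were those of Selenom, a selenoprotein of the endoplasmic reticulum (0.46, unadjusted p = 0.0031), and Neat1 (0.63, unadjusted p = 0.00861). The count stayed at 0 with beadchip as a block, under median scaling and with any 1 array left out.

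Small shifts passed the test for 3 lists at 1 kHz, each with 0 genes called, alone or adjusted over the list alone, and 0 of them held with an estimated correlation. Replication-dependent and linker histone genes (41 measured, among them H3c4 at 0.32) lay higher, with a median of 0.20 (adjusted p = 1.26e-05; adjusted p = 0.53 with an estimated correlation), 0.11 with beadchip as a block and 0.14 within the shared beadchip. Immediate early genes (22 measured, among them Junb at -0.35) had a median of -0.13 (adjusted p = 0.0294; adjusted p = 0.68 with an estimated correlation), and -0.04 with beadchip as a block (adjusted p = 0.126) and -0.10 within the shared beadchip. Their shift was lost without untreated replicate 1 (adjusted p = 0.401) or 3 (0.242) and without 1 kHz replicate 1 (0.051) or 2 (0.156). Splicing regulators (19 measured, among them Srsf5 and the kinase gene Clk4) had a median of -0.13 (adjusted p = 0.0227; adjusted p = 0.68 with an estimated correlation), -0.12 with beadchip as a block (adjusted p = 0.0935) and within the shared beadchip. The splicing shift was lost without untreated replicate 3 (adjusted p = 0.105) or 1 kHz replicate 2 (0.198). The heat shock list had a median of 0.01 (adjusted p = 0.268).

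The comparison of the frequencies asked which transcripts differed between 1 and 18 kHz at the same voltage and time. Of 22 immediate early genes 9 were higher at 1 kHz than at 18 kHz, and 13, among them Jun and Egr1 (0.13, adjusted p = 0.784), did not pass. Fos was 58.5-fold higher at 1 kHz (11.82 ± 0.20 against 5.95 ± 0.51; adjusted p = 4.66e-05) and Fosb at least 7.57-fold higher (adjusted p = 4.66e-05). Dusp1 was higher by 3.17 (11.07 ± 0.01 against 7.90 ± 0.34; adjusted p = 0.00116). Csrnp1, Osm and Ier3 were higher by 1.88 to 2.76, and Dusp2 and Mir17hg at least 4.34-fold and 4.43-fold. Each of these held whichever array was left out. Egr2 was at least 8.36-fold higher (adjusted p = 0.00739, and 0.0519 without 1 kHz replicate 3). Lower at 1 kHz were Arhgef2 (-2.25, adjusted p = 0.00467) and Bach1, a repressor of heme and antioxidant genes (3.24-fold lower, adjusted p = 0.00388). Stress genes that did not pass included Dnajb1 (0.13), Hsph1 (-0.33, adjusted p = 0.156), Hspa8 (0.05), Jun (0.52, adjusted p = 0.336) and Ddit3 (-0.12, adjusted p = 0.712). Under median scaling Ddit3 had the other sign (1.22, adjusted p = 0.0364), where the median of all genes moved by 1.13.

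Between the frequencies 4 lists shifted, all higher at 1 kHz, and 0 held with an estimated correlation. Of the 22 immediate early genes 9 were higher and 0 lower (11 higher adjusted over the list alone). Their median was 0.84 (0.61 with bounds; adjusted p = 6.86e-08; adjusted p = 0.316 with an estimated correlation). It was 0.84 with beadchip as a block and 0.53 and 0.93 within the beadchips. Of 12 NF-kB targets 3 were higher (5 adjusted over the list alone), among them Ccl3 (at least 3.39-fold, adjusted p = 0.00739) and Nfkbiz (1.97, adjusted p = 0.0113, and up to 0.0707 without 1 kHz replicate 1 or 3). Their median was 0.49 (adjusted p = 0.00119; adjusted p = 0.316 with an estimated correlation), 0.53 with beadchip as a block and 0.61 and 0.46 within the beadchips. Of 24 G1/S genes 1 was higher (2 adjusted over the list alone). Their median was 0.24 (0.21 with bounds; adjusted p = 0.019, and 0.12 without 18 kHz replicate 3; adjusted p = 0.316 with an estimated correlation), and 0.24 with beadchip as a block and 0.32 and 0.20 within the beadchips. Of 19 unfolded protein response genes 1 was higher (2 adjusted over the list alone), Dnajb9 (0.69, adjusted p = 0.0299, and up to 0.146 without 18 kHz replicate 1 or any 1 kHz array). The median of that list was 0.23 (adjusted p = 0.0469; adjusted p = 0.68 with an estimated correlation), and its shift was lost with beadchip as a block (0.22, adjusted p = 0.0772), within one beadchip (0.15, adjusted p = 0.109), without 18 kHz replicate 2 (adjusted p = 0.176) or 3 (0.0722) and without 1 kHz replicate 3 (0.0684). The heat shock list had a median of 0.19 (adjusted p = 0.268).

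In this comparison 231 genes differed, 78 higher and 153 lower at 1 kHz, with 2605 at an unadjusted p below 0.05 and 28.1% of genes with groups that did not overlap. With beadchip as a block 111 genes passed, and within the beadchips 2747 and 0. The count was 104 and 2557 without 18 kHz replicates 1 and 3, 24, 59 and 25 without 1 kHz replicates 1, 2 and 3, and 75 without both dimmer 18 kHz arrays, with the spread of the array left taken from the other groups. Without those 2 arrays Egr2 (3.05, adjusted p = 0.0505) and Dnajb9 (0.75, adjusted p = 0.0894) did not pass, though Dnajb9 differed as much as before, and Jun, not detected on the array left, newly passed (adjusted p = 0.0269). Median scaling moved the median of all genes by 1.13 log2 and gave 5107 genes higher and 1 lower.

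The comparison of 42 °C with untreated cells asked for the response to mild heat shock. Heating at 42 °C raised 7 of 22 genes of the classical heat shock response, with the inducible chaperones first. Hspa1a (probe 2350017), the inducible HSP70, was detected on 0 of 3 untreated arrays and rose at least 10.5-fold to 8.57 ± 0.19 (adjusted p = 2.05e-09). Dnajb1 rose 15.7-fold from 10.90 ± 0.10 to 14.87 ± 0.08 (adjusted p = 7.68e-10) and Hsph1 11.8-fold from 10.04 ± 0.19 to 13.60 ± 0.32 (adjusted p = 7.77e-07). Hspa1b, a second inducible HSP70 gene, rose at least 2.67-fold (adjusted p = 9.75e-07), and Hspa4l, an HSP110 relative, by 2.66 on 1 probe, while its other probe did not pass (-0.07, adjusted p = 0.928). Jun rose 9.53-fold from 5.28 ± 0.36, detected on 2 of 3 untreated arrays, to 8.54 ± 0.22 (adjusted p = 1.83e-05), and the transcription factor gene Egr1 rose by 1.75 (adjusted p = 0.00221). Prf1, the perforin gene, rose by 3.46. Fosb fell 10.1-fold from 8.77 ± 0.13 to 5.43 ± 0.19 (adjusted p = 7.77e-07) and Fos by 1.20 to 9.66 ± 0.39 (adjusted p = 0.0071). Ngp, a neutrophil granule protein, fell by 2.94 (adjusted p = 7.37e-06) and the cytokine Osm by 1.95 (adjusted p = 3.65e-05). Hspa8 (0.25, adjusted p = 0.407), Hmox1 (0.59, adjusted p = 0.174) and Ddit3 (-0.47, adjusted p = 0.445) did not pass.

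At 42 °C 6 lists shifted, 1 upward and 5 downward. Of 22 heat shock genes 7 rose and 0 fell (10 rose adjusted over the list alone), and this was the shift that held with an estimated correlation (median 0.35; adjusted p = 2.14e-12, and 0.0204 with an estimated correlation). It was 0.39 with beadchip as a block and 0.49 and 0.35 within the beadchips. Of 23 immediate early genes 2 rose, Jun and Egr1, and 5 fell (2 and 8 adjusted over the list alone), including Fosb and Dusp2 (-1.89). Their median was -0.38 (-0.41 with bounds; adjusted p = 0.00402; adjusted p = 0.289 with an estimated correlation), -0.45 to -0.19 with 1 array left out, -0.27 with beadchip as a block and -0.27 (adjusted p = 0.0654) and -0.53 within the beadchips. Of 16 genes downstream of interleukin 3 and STAT5, 1 fell (4 adjusted over the list alone), Osm, with a median of -0.37 (-0.34 with bounds; adjusted p = 0.000111; adjusted p = 0.0803 with an estimated correlation), -0.36 with beadchip as a block and -0.21 and -0.35 within the beadchips. Of 12 NF-kB targets 3 fell (3 adjusted over the list alone), including the inhibitor gene Nfkbia (-1.56, adjusted p = 0.000637) and the chemokine gene Ccl4 (-2.03, adjusted p = 0.00243). Their median was -0.21 (adjusted p = 0.0247, and 0.0867 without 42 °C replicate 1; adjusted p = 0.364 with an estimated correlation), and it did not pass with beadchip as a block (-0.20, adjusted p = 0.0613) or within either beadchip (-0.23 and -0.18). Of 20 cholesterol genes 1 fell (1 adjusted over the list alone), Insig1, which restrains sterol synthesis (-1.10, adjusted p = 0.00499), with a median of -0.31 (adjusted p = 0.00175; adjusted p = 0.411 with an estimated correlation), -0.35 with beadchip as a block and -0.23 and -0.29 within the beadchips. Of 19 unfolded protein response genes 1 fell (2 adjusted over the list alone), Herpud1 (-0.56, adjusted p = 0.0387, and up to 0.148 without any array but untreated replicate 2). Their median was -0.25 (adjusted p = 0.0202, and 0.0735 without untreated replicate 2; adjusted p = 0.262 with an estimated correlation), -0.25 with beadchip as a block and -0.28 and -0.23 (adjusted p = 0.324) within the beadchips.

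At 42 °C 267 of 9544 genes changed, 135 higher and 132 lower, 255 of them by at least 1.5-fold. There were 1552 genes at an unadjusted p below 0.05, and 28.7% of genes had groups that did not overlap. A fit with beadchip as a block passed 410 genes, and 17 and 15 within the beadchips. The count was 165, 156 and 148 without untreated replicates 1, 2 and 3, and 160 and 133 without 42 °C replicates 1 and 3. Median scaling moved the median of all genes by -0.13 and gave 77 genes higher and 179 lower.

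The comparison of 47 °C with untreated cells asked for the response to stronger heat. At 47 °C 10 of 23 immediate early genes fell and 13, among them Jun and Egr1 (-0.19, adjusted p = 0.675), did not pass, while the heat shock genes that had risen at 42 °C did not pass. Dusp1 fell 9.34-fold from 11.16 ± 0.11 to 7.94 ± 0.42 (adjusted p = 5.03e-05), Fos 8.11-fold from 10.86 ± 0.04 to 7.83 ± 0.29 (adjusted p = 1.19e-05) and Fosb at least 10.7-fold, with detection left on 1 of 3 arrays (adjusted p = 7.67e-07). Egr2 fell 13.6-fold (adjusted p = 7.44e-05; detected on 2 of 3 arrays at 47 °C), the chemokine gene Ccl3 11.2-fold (adjusted p = 0.00032) and the mRNA decay factor gene Zfp36 6.46-fold (adjusted p = 0.00084). Dnajb1 changed by -0.15 (adjusted p = 0.429), Hsph1 by 0.19 (adjusted p = 0.571), Hspa8 by -0.11 (adjusted p = 0.636) and Jun by -0.32 (adjusted p = 0.47), and Hspa1a and Hspa1b were at background in both groups. Clec2d rose 2.89-fold (adjusted p = 0.00062). Rpph1, the RNA of RNase P, was detected on 0 of 3 untreated arrays and rose at least 2.26-fold (adjusted p = 0.00105).

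At 47 °C 10 lists shifted, 2 upward and 8 downward, and 0 held with an estimated correlation. Of 23 immediate early genes 0 rose and 10 fell (1 and 14 adjusted over the list alone). Their median was -0.61 (-0.58 with bounds; adjusted p = 4.89e-09; adjusted p = 0.0665 with an estimated correlation), -0.61 with beadchip as a block and -0.62 and -0.64 within the beadchips. Of 19 splicing regulators 1 rose and 5 fell (1 and 8 adjusted over the list alone), led by Srsf6 (-0.90, adjusted p = 0.00175), with a median of -0.37 (adjusted p = 3.29e-05; adjusted p = 0.153 with an estimated correlation) and -0.40 and -0.25 within the beadchips. Of 47 histone genes 11 rose and 1 fell (13 and 1 adjusted over the list alone), led by H4c4 (0.92, adjusted p = 0.00767), with a median of 0.42, which under median scaling was -0.04, or 0.39 relative to the shift of all genes (adjusted p = 0.000111; adjusted p = 0.363 with an estimated correlation), and 0.33 and 0.59 within the beadchips. Of 12 NF-kB targets 5 fell (5 adjusted over the list alone), including Nfkbia (-1.63, adjusted p = 0.000784) and Nfkbiz (-1.60, adjusted p = 0.006), with a median of -0.34 (adjusted p = 0.00221; adjusted p = 0.258 with an estimated correlation) and -0.33 and -0.45 within the beadchips. Of 20 cholesterol genes 4 fell (1 rose and 6 fell adjusted over the list alone), including Insig1 (2.01-fold lower, adjusted p = 0.00875), with a median of -0.30 (adjusted p = 0.00231; adjusted p = 0.411 with an estimated correlation) and -0.27 and -0.46 within the beadchips. Of 19 unfolded protein response genes 1 rose and 2 fell (1 and 5 adjusted over the list alone). Xbp1, their transcription factor, rose by 0.52, and Sdf2l1 fell by 0.70 and Dnajb9 by 0.79. These calls were lost without any array, except that Xbp1 passed without 47 °C replicate 1 and Sdf2l1 without untreated replicate 1 (adjusted p up to 0.114). The list's median was -0.39 (-0.32 with bounds; adjusted p = 0.00443; adjusted p = 0.188 with an estimated correlation), and -0.30 (adjusted p = 0.0805 on one) within both beadchips. Of 10 myeloid genes 2 rose (2 adjusted over the list alone), the granulocyte factor gene Cebpe (0.57, adjusted p up to 0.0539 without untreated replicate 3 or 47 °C replicate 2) and the protease gene Ctsg (0.71; lost without any 1 of 6 arrays, adjusted p up to 0.104), with a median of 0.49 (adjusted p = 0.0107; adjusted p = 0.153 with an estimated correlation) and 0.43 and 0.67 within the beadchips.

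The other lists moved little at 47 °C. Of 25 oxidative stress genes 1 fell (0 adjusted over the list alone), the autophagy receptor gene Sqstm1 (-0.87, adjusted p = 0.0407, and up to 0.141 without any array but untreated replicate 1). Their median was -0.13 (adjusted p = 0.0277; adjusted p = 0.239 with an estimated correlation), with adjusted p of 0.0539, 0.0561 and 0.0713 without untreated replicates 1 and 2 and 47 °C replicate 3, and -0.16 and -0.19 (adjusted p = 0.154) within the beadchips. Of 24 ribosome biogenesis genes 2 fell (2 adjusted over the list alone), Rrs1 and Polr1b, both by 0.66 and both lost without any array but 47 °C replicate 1 (adjusted p up to 0.128). Their median was -0.18 (adjusted p = 0.0247; adjusted p = 0.567 with an estimated correlation), with adjusted p of 0.074 without untreated replicate 2 and 0.0614 without 47 °C replicate 2, and -0.19 and -0.21 (adjusted p = 0.0645) within the beadchips. Of 24 G1/S genes 1 fell (0 adjusted over the list alone), the helicase gene Mcm3 (-0.65, adjusted p = 0.0493, and up to 0.169 without any array but 47 °C replicate 1). Their median was -0.17 (adjusted p = 0.0225; adjusted p = 0.236 with an estimated correlation), with adjusted p of 0.0539 without untreated replicate 1 and 0.0501 without 47 °C replicate 2, and -0.09 (adjusted p = 0.0838) and -0.27 within the beadchips. The 22 heat shock genes had 0 called and a median of -0.04 (adjusted p = 0.5). Untreated and 47 °C arrays were spread over the beadchips alike, and beadchip as a block left all these medians at their values.

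At 47 °C 791 genes changed, 425 higher and 366 lower, 642 of them by at least 1.5-fold. There were 2493 genes at an unadjusted p below 0.05, and 34.7% of genes had groups that did not overlap. With beadchip as a block 991 genes passed, and 481 and 0 within the beadchips. The count was 422, 236 and 218 without untreated replicates 1, 2 and 3, and 431, 419 and 236 without 47 °C replicates 1, 2 and 3. Median scaling moved the median of all genes by -0.43 and gave 62 genes higher and 2747 lower.

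**Figure D2:**
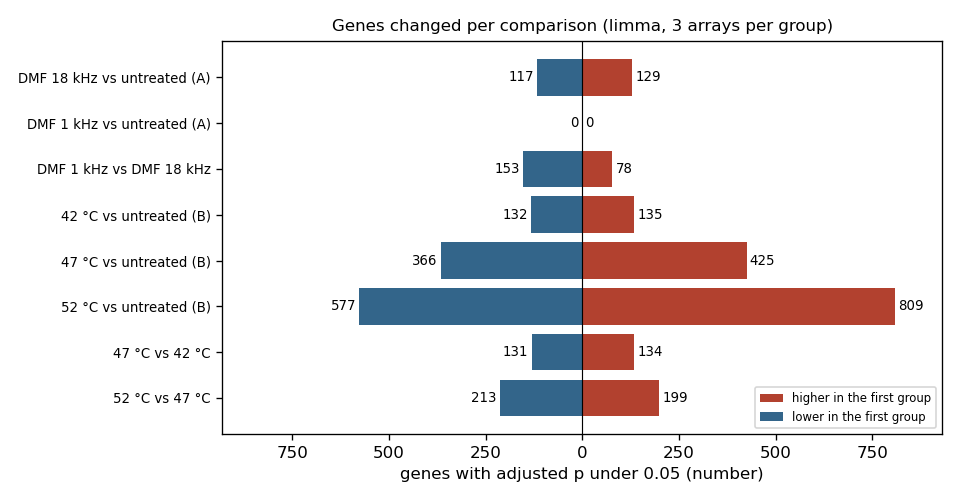
Number of genes (x axis) higher and lower at an adjusted p below 0.05 in each of 8 comparisons (y axis), 3 arrays per group. Bars run from 0 genes at 1 kHz to 809 higher and 577 lower at 52 °C, a split that median scaling turned to 143 higher and 2839 lower.

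The comparison of 52 °C with untreated cells asked for the response to the strongest heat. At 52 °C 11 of 23 immediate early genes fell and 2 rose. Fos fell 24.6-fold to 6.24 ± 0.28 (adjusted p = 1.35e-07), Fosb at least 11.5-fold (adjusted p = 1.35e-07), Egr2 at least 18.6-fold with detection on 1 of 3 arrays (adjusted p = 2.23e-05) and Dusp1 10.9-fold (adjusted p = 2.23e-05). Ccl3 fell at least 12.5-fold, and the cytokine gene Il4 (-3.38) and Csrnp1 (-3.02) fell too. Clec2d rose 7.26-fold from 6.87 ± 0.14 to 9.73 ± 0.09 (adjusted p = 2.29e-06) and Arhgef2 by 2.80 (adjusted p = 0.000283). Itga2b, the platelet integrin, rose by 1.33 (adjusted p = 0.000467). Replicates 2 and 3 at 52 °C stood apart from replicate 1, and some large changes rested on them. Klf1, an erythroid transcription factor, rose by 1.09 (adjusted p = 0.00585) but by 0.51 in replicate 1 alone (adjusted p = 0.151). Hdc, which makes histamine, fell by 2.58 and by 1.11 in replicate 1 (adjusted p = 0.0185). Fos (-4.35, adjusted p = 9.37e-05), Dusp1 (-3.97, adjusted p = 0.000383), Clec2d (2.77, adjusted p = 0.000898) and Arhgef2 (2.06, adjusted p = 0.0185) passed with replicate 1 alone, whose spread was then taken from the other groups. Dnajb1 (-0.36, adjusted p = 0.0528), Hsph1 (0.23), Hspa8 (-0.33, adjusted p = 0.129) and Jun (0 of 3 arrays with detection at 52 °C, adjusted p = 0.174) did not pass.

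At 52 °C 9 lists shifted, 2 upward and 7 downward, and 0 held with an estimated correlation. Of 23 immediate early genes 2 rose and 11 fell (2 and 11 adjusted over the list alone). Their median was -0.55 (-0.44 with bounds; adjusted p = 2.02e-07; adjusted p = 0.0859 with an estimated correlation), -0.69 with beadchip as a block and -0.70 and -0.50 within the beadchips. Of 20 cholesterol genes 5 fell (10 adjusted over the list alone), among them Ebp, a sterol isomerase (-0.86, adjusted p = 0.00347), and Insig1 (-0.85, adjusted p = 0.0117, and 0.0512 without 52 °C replicate 2). Their median was -0.60 (-0.49 with bounds; adjusted p = 7.29e-06; adjusted p = 0.307 with an estimated correlation), -0.65 with beadchip as a block and -0.72 and -0.57 within the beadchips. Of 19 unfolded protein response genes 4 fell (1 rose and 6 fell adjusted over the list alone), led by Sdf2l1, a chaperone cofactor (-0.96, adjusted p = 0.00486), with a median of -0.41 (adjusted p = 0.00234; adjusted p = 0.153 with an estimated correlation), -0.46 with beadchip as a block and -0.32 and -0.33 within the beadchips. Of 12 NF-kB targets 4 fell (4 adjusted over the list alone), including Nfkbiz (-2.57, adjusted p = 0.00019) and Nfkbia (-1.14, adjusted p = 0.00381), with a median of -0.31 (adjusted p = 0.00298; adjusted p = 0.263 with an estimated correlation), -0.34 with beadchip as a block and -0.60 and -0.25 within the beadchips. Of 6 erythroid and megakaryocyte genes 2 rose (3 adjusted over the list alone), Itga2b and Klf1, with a median of 0.74 (adjusted p = 0.00608; adjusted p = 0.23 with an estimated correlation), 0.83 with beadchip as a block and 1.05 and 0.80 (adjusted p = 0.0587) within the beadchips. Replicates 2 and 3 carried part of this shift: in replicate 1 alone Itga2b passed (1.21, adjusted p = 0.0339), Klf1 did not and the hemoglobin gene Hba-a1 was not detected. Of the other genes named for these lists, Nfkbiz and Nfkbia passed in replicate 1 alone, and Ebp (-0.58, adjusted p = 0.122), Insig1 (-0.93, adjusted p = 0.126) and Sdf2l1 (-0.80, adjusted p = 0.131) did not.

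Further shifts at 52 °C were nearer the threshold. Of 27 proteasome genes 4 fell (4 adjusted over the list alone), among them Psmb6 (-0.52, adjusted p = 0.0126, and 0.051 without 52 °C replicate 3), with a median of -0.23 (adjusted p = 0.0112; adjusted p = 0.381 with an estimated correlation), -0.36 to -0.11 with 1 array left out, -0.19 with beadchip as a block and -0.33 and -0.18 (adjusted p = 0.265) within the beadchips. Of 20 membrane repair genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), among them the annexin genes Anxa4 (0.77) and Anxa1 (-1.66), which were lost without untreated replicate 1 or 2 or 52 °C replicate 2 or 3, and Anxa1 also without untreated replicate 3 (adjusted p up to 0.0955). Their median was 0.37, which under median scaling was -0.12, or 0.29 relative to the shift of all genes (adjusted p = 0.0225, and 0.0524 without untreated replicate 1; adjusted p = 0.307 with an estimated correlation), 0.40 with beadchip as a block and 0.29 (adjusted p = 0.0918) and 0.41 within the beadchips. Of 8 mast cell and basophil genes 2 fell (5 adjusted over the list alone), Hdc and Ms4a2, a chain of the IgE receptor (-0.92, adjusted p = 0.0364, and up to 0.141 without any array but 52 °C replicate 1). Their median was -0.96 (adjusted p = 0.0291; adjusted p = 0.517 with an estimated correlation), lost without 52 °C replicate 2 (adjusted p = 0.0651) or 3 (0.0659), -1.07 with beadchip as a block and -1.76 and -0.63 (adjusted p = 0.329) within the beadchips. Of 24 ribosome biogenesis genes 4 fell (4 adjusted over the list alone), among them Nop58, a small nucleolar RNA protein (-1.32, adjusted p = 0.011, and 0.0547 without 52 °C replicate 2). Their median was -0.18 (adjusted p = 0.0483; adjusted p = 0.607 with an estimated correlation), lost without untreated replicate 2 (adjusted p = 0.12), without 52 °C replicate 2 (0.106) or 3 (0.178) and with beadchip as a block (-0.18, adjusted p = 0.0613), and -0.32 and -0.15 (adjusted p = 0.458) within the beadchips. Of 22 heat shock genes 2 fell (1 adjusted over the list alone), the ubiquitin gene Ubb (-0.58, adjusted p = 0.0179, and up to 0.0855 without untreated replicate 2 or 3 or 52 °C replicate 2) and the co-chaperone gene Dnajb4 (-0.75; lost without untreated replicate 1 or 3 or 52 °C replicate 2 or 3, adjusted p up to 0.164), and the list had a median of 0.00 (adjusted p = 0.438). In replicate 1 alone Ubb (-0.63), Psmb6 (-0.48), Anxa4 (0.62), Nop58 (-0.89), Dnajb4 (-0.31), Anxa1 (-0.29) and Ms4a2 (-0.26) did not pass (adjusted p from 0.116 for Ubb to 0.606 for Ms4a2), with Ubb and Psmb6 about as low as in all 3.

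At 52 °C 1386 genes changed, 809 higher and 577 lower, 1041 of them by at least 1.5-fold. There were 2999 genes at an unadjusted p below 0.05, and 31.6% of genes had groups that did not overlap. A fit with beadchip as a block passed 1878 genes, and 888 and 6 within the beadchips. The count was 759, 780 and 608 without untreated replicates 1, 2 and 3, and 2801, 424 and 562 without 52 °C replicates 1, 2 and 3. With 52 °C replicate 1 alone it was 130, of which 106 were among the 1386. Median scaling moved the median of all genes by -0.41 and gave 143 genes higher and 2839 lower.

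The comparison of 47 with 42 °C asked how the response differed between strong and mild heat. Chaperone genes that 42 °C had raised were much lower at 47 °C, and some myeloid granule genes were higher. Dnajb1 was 17.4-fold lower (adjusted p = 4.83e-10), Hspa1a at least 9.43-fold, Hsph1 10.3-fold (adjusted p = 1.07e-06) and Jun at least 8.50-fold (adjusted p = 7.1e-06). Dusp1 (-3.28, adjusted p = 1.29e-05), Egr2 (-2.90, adjusted p = 0.000404) and Fos (-1.82, adjusted p = 0.000408) were lower too. Ngp was higher by 3.34 (adjusted p = 2.01e-06), the lactoferrin gene Ltf by 3.01 (adjusted p = 8.45e-06), Stfa2, a cysteine protease inhibitor, by 2.29 (adjusted p = 2.01e-06) and S100a9, a partner of S100a8, by 2.14 (adjusted p = 0.00742). S100a8 was higher by 2.49 (adjusted p = 0.0117, and up to 0.051 without 42 °C replicate 2 or 47 °C replicate 2). Clec2d was higher by 2.18 (adjusted p = 1.24e-05).

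Between 47 and 42 °C 5 lists shifted, and those of the heat shock and myeloid genes held with an estimated correlation. Of 22 heat shock genes 8 were lower and 0 higher at 47 °C (12 lower adjusted over the list alone). Their median was -0.40 (adjusted p = 7.56e-16, and 0.0204 with an estimated correlation), -0.40 with beadchip as a block and -0.49 and -0.47 within the beadchips. Of 10 myeloid genes 4 were higher (7 adjusted over the list alone), among them S100a8, S100a9 and Lyz1, a lysozyme (0.86, adjusted p = 0.0303, and up to 0.118 without any array but 47 °C replicate 1). Their median was 0.70 (adjusted p = 6.26e-07, and 0.0204 with an estimated correlation), 0.69 with beadchip as a block and 0.56 and 0.96 within the beadchips. Of 47 histone genes 9 were higher (23 adjusted over the list alone), led by H2bc18, at least 1.72-fold (adjusted p = 0.00426), with a median of 0.45 (adjusted p = 7.59e-11; adjusted p = 0.153 with an estimated correlation), 0.43 with beadchip as a block and 0.34 and 0.66 within the beadchips. Of 23 immediate early genes 6 were lower (2 higher and 7 lower adjusted over the list alone). Their median was -0.24 (-0.22 with bounds; adjusted p = 4.05e-05; adjusted p = 0.153 with an estimated correlation), -0.33 with beadchip as a block and -0.34 and -0.19 (adjusted p = 0.0712) within the beadchips. Of 19 splicing regulators 2 were lower (1 higher and 7 lower adjusted over the list alone), the kinase genes Clk1 (-0.80) and Clk4 (-0.55), both lost without 42 °C replicate 3 or 47 °C replicate 3, Clk1 also without 42 °C replicate 2 and Clk4 also without 42 °C replicate 1 or 47 °C replicate 1 or 2 (adjusted p up to 0.158). Their median was -0.22 (adjusted p = 0.015; adjusted p = 0.307 with an estimated correlation), -0.18 with beadchip as a block and -0.09 (adjusted p = 0.289) and -0.23 within the beadchips.

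In this comparison 265 genes differed, 134 higher and 131 lower at 47 °C, with 1600 at an unadjusted p below 0.05 and 24.3% of genes with groups that did not overlap. With beadchip as a block 333 genes passed, and 46 and 5 within the beadchips. The count was 146 and 105 without 42 °C replicates 1 and 3, and 151 and 152 without 47 °C replicates 2 and 3. Median scaling moved the median of all genes by -0.31 and gave 47 genes higher and 380 lower.

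The comparison of 52 with 47 °C asked what the last step of heat added. Of 10 myeloid and 8 mast cell genes, 4 and 5 were lower at 52 °C than at 47 °C, and chaperone genes did not pass the test. Mpo (probe 940309), the myeloperoxidase gene, was 5.53-fold lower (7.59 ± 0.43 against 10.05 ± 0.26; adjusted p = 0.000488) and Ctsg (probe 7650682), the cathepsin G gene, 4.34-fold lower (9.59 ± 0.45 against 11.71 ± 0.13; adjusted p = 0.000488). The tryptase gene Tpsab1 was at least 5.37-fold lower with detection on 1 of 3 arrays at 52 °C (adjusted p = 0.0133), and Ms4a2 was lower by 1.69 (adjusted p = 0.0119). Replicates 2 and 3 at 52 °C carried much of this fall. In replicate 1 alone Mpo (-1.98, adjusted p = 0.0175) and Ctsg (-1.62, adjusted p = 0.00386) passed, while Tpsab1 (-1.41, adjusted p = 0.053) and Ms4a2 (-1.03, adjusted p = 0.0501) did not. Fos was lower by a further 1.60 (adjusted p = 0.00427). Clec2d (1.33, adjusted p = 0.00427) and Ptgs1, a cyclooxygenase gene (1.25, adjusted p = 0.000619), were higher. Dnajb1 (-0.21) and Hsph1 (0.04) did not pass.

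Between 52 and 47 °C 5 lists shifted, 1 upward and 4 downward, and 0 held with an estimated correlation. Of 8 mast cell and basophil genes 5 were lower (6 adjusted over the list alone), among them Ms4a2 and Hdc (-2.50, adjusted p = 0.0161, and up to 0.0607 without 47 °C replicate 2 or 3 or 52 °C replicate 3), with a median of -1.66 (adjusted p = 3.29e-05; adjusted p = 0.296 with an estimated correlation), -1.69 with beadchip as a block and -2.14 and -1.67 within the beadchips. In 52 °C replicate 1 alone Hdc passed (-1.04, adjusted p = 0.0303), and Mcpt8 (-0.87, adjusted p = 0.167) and Cpa3 (-0.45, adjusted p = 0.344), proteases of mast cells and basophils, did not. Of 10 myeloid genes 4 were lower (1 higher and 7 lower adjusted over the list alone), among them Mpo and Ctsg, with a median of -0.63 (adjusted p = 8.83e-05; adjusted p = 0.0584 with an estimated correlation), -0.65 with beadchip as a block and -0.94 and -0.68 within the beadchips. Of 47 histone genes 7 were lower (18 adjusted over the list alone), among them H4c9 (-0.89, adjusted p = 0.012, 0.0523 without 47 °C replicate 3 and 0.0521 in 52 °C replicate 1 alone), with a median of -0.49 (adjusted p = 9.74e-11; adjusted p = 0.153 with an estimated correlation), -0.50 with beadchip as a block and -0.27 and -0.76 within the beadchips. The 44 oxidative phosphorylation genes, among them Ndufv1 (-0.45, adjusted p = 0.0854), had 0 called, alone or adjusted over the list alone, and a median of -0.16 (adjusted p = 0.00171; adjusted p = 0.153 with an estimated correlation), -0.15 with beadchip as a block and -0.16 and -0.15 within the beadchips. The 19 splicing regulators, among them Srsf6 (0.46, adjusted p = 0.0518), had 0 called (1 higher adjusted over the list alone) and a median of 0.23 (adjusted p = 0.0225, and 0.0936 without 52 °C replicate 1; adjusted p = 0.339 with an estimated correlation), 0.21 with beadchip as a block and 0.25 (adjusted p = 0.0674) and 0.23 (adjusted p = 0.126) within the beadchips. The heat shock list (22 genes, 0 called) had a median of 0.02 but a mean of -0.03 (adjusted p = 0.819), and 1 of 23 immediate early genes was lower (3 adjusted over the list alone; median -0.16, and 0.00 with bounds; adjusted p = 0.369).

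In this comparison 412 genes differed, 199 higher and 213 lower at 52 °C, with 2233 at an unadjusted p below 0.05 and 22.4% of genes with groups that did not overlap. A fit with beadchip as a block passed 755 genes, and 15 and 0 within the beadchips. The count was 81 and 42 without 47 °C replicates 2 and 3, and 1238, 119 and 49 without 52 °C replicates 1, 2 and 3. With 52 °C replicate 1 alone it was 218, of which 66 were among the 412. Median scaling moved the median of all genes by 0.03 and gave 49 genes higher and 61 lower.

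**Figure D3:**
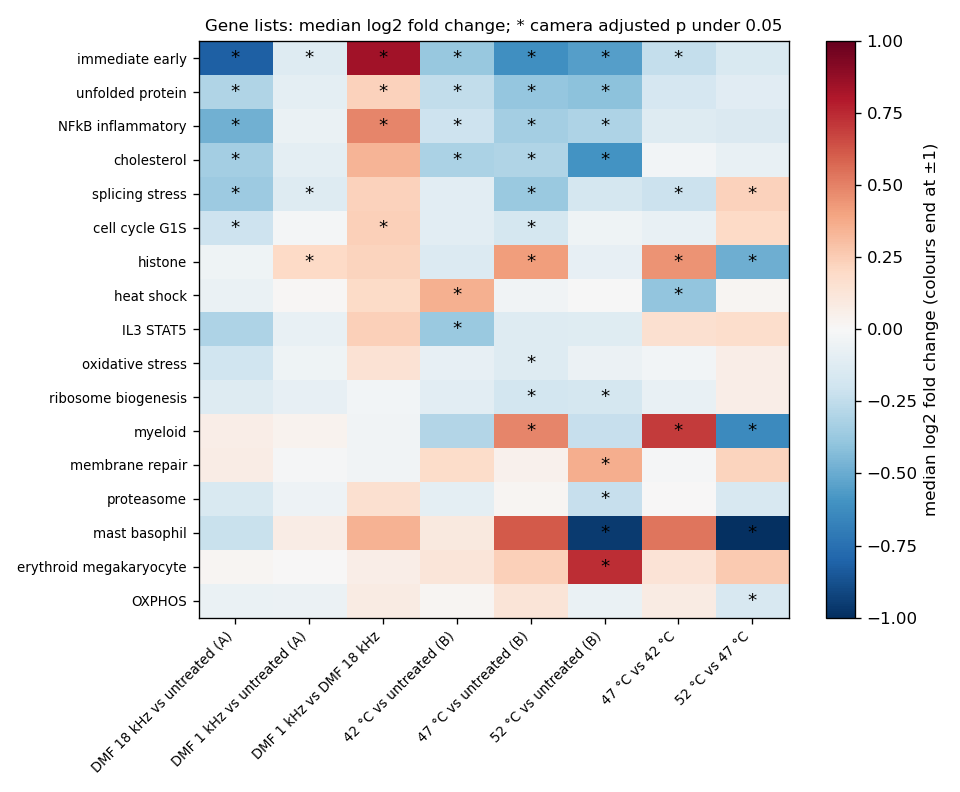
Median log2 fold change (colour, ending at -1 and 1) of 17 gene lists (y axis) in 8 comparisons (x axis), with a star at an adjusted p below 0.05 from the camera test. Immediate early genes were lower at 18 kHz (-0.82), 42 °C (-0.38), 47 °C (-0.61) and 52 °C (-0.55), with none of these 4 shifts held at an estimated correlation; under median scaling histone genes at 47 °C (-0.04) and membrane repair genes at 52 °C (-0.12) changed sign, where all genes moved by a median of -0.43 and -0.41.

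The last comparison set the effect of actuation, against the untreated cells of batch A, beside the effect of heat, against those of batch B, over 8764 genes read by the same probe. Some immediate early genes fell at 18 kHz as at 47 and 52 °C, and the chaperone response of 42 °C had no counterpart in actuation. Across genes, which are not independent replicates, the 18 kHz effect correlated with that of 47 °C at Pearson's r = 0.487 (Spearman's coefficient 0.414), of 52 °C at 0.419 (0.373) and of 42 °C at 0.272 (0.253). The 1 kHz effect correlated at 0.151 (0.188), 0.193 (0.232) and 0.161 (0.188) in the same order. Of 105 genes lower at 18 kHz, 41 were also lower at 47 °C against 4.13 for independent lists (Fisher's exact test, one of 6 such tests, p = 6.41e-31), 51 at 52 °C against 6.35 and 14 at 42 °C against 1.52. Of 112 genes higher at 18 kHz, 24, 31 and 4 were also higher at 47, 52 and 42 °C against 5.07, 9.79 and 1.42.

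The tests of the difference between effects gave 179 genes for 18 kHz against 42 °C, 83 with a higher and 96 with a lower effect at 18 kHz. The effects on Dnajb1 (-4.42, adjusted p = 6.87e-12), Hsph1 (-3.13, adjusted p = 4.06e-07) and Jun (-3.72, adjusted p = 0.000127) were lower at 18 kHz than at 42 °C, as were those on Fos (-5.43, adjusted p = 2.07e-08) and Dusp1 (-3.52, adjusted p = 2.69e-05). For 18 kHz against 47 °C 21 genes differed, among them Fos (-3.69, adjusted p = 3.49e-05), Dusp2 (lower) and Neat1 (2.72, adjusted p = 0.00161). The effects on Dusp1 (-0.36, adjusted p = 0.69) and Dnajb1 (-0.32, adjusted p = 0.375) did not pass that test. For 18 kHz against 52 °C 123 genes differed, with Fos (-2.17, adjusted p = 0.0113) and Junb (-0.90, adjusted p = 0.0416) again lower at 18 kHz. Fos fell from 12.19 to 5.95 at 18 kHz (2 of 3 arrays with detection) and from 10.86 to 6.24 at 52 °C. A higher start was thus not told apart from a larger response. For 1 kHz 58 genes differed from 42 °C, among them Dnajb1 (-4.28, adjusted p = 1.22e-11) and Fosb (3.46, adjusted p = 2.16e-06). From 47 °C 15 genes differed, among them Fosb (higher), Dusp1 (2.99, adjusted p = 0.000867) and Fos (2.51, adjusted p = 0.00198). From 52 °C 171 differed, among them Fos (4.03, adjusted p = 4.27e-06) and Clec2d (-1.92, adjusted p = 0.00341). With 1 array left out these 6 counts ran over 97 to 1100, 17 to 703, 30 to 1080, 37 to 54, 9 to 14 and 53 to 1076 in the order given here. Batch and treatment are confounded except through each batch's untreated group, so that only differences of effects were compared.

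**Figure D4:**
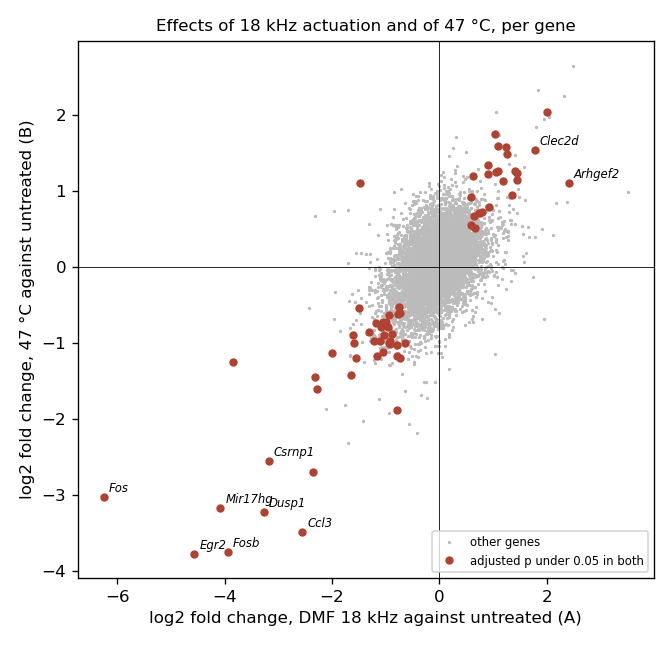
Log2 fold change at 18 kHz (x axis) against that at 47 °C (y axis), each against the untreated cells of its batch, with a point per gene measured by the same probe and red for genes at an adjusted p below 0.05 in both. Across the 8764 genes Pearson's r was 0.487, and Fos lay at -6.25 and -3.02.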

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

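Each test of an explanation in this part was chosen after the result was seen, and the tests of dim arrays and of warming replaced earlier versions whose results had been seen (the medians of the immediate early list, -0.816, beside -0.061 for matched lists under quantile normalization, and of the heat shock list at 18 kHz, -0.063).

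A test of the difference itself found genes whose response to actuation differed from that to heat in all 6 pairings. The arrays of each batch were also divided in other ways, 100 splits per pairing with the real one included. For 18 kHz against 42 °C only the real split of the 100 gave as many genes (real 179, highest other 147). That is the smallest share 100 splits can give and the lowest of the 6 pairings, so that chance is not excluded over the 6. The count was 97 to 136 without any 1 array but 18 kHz replicate 3. Nor can chance be excluded for the rest. As many genes came from 14 splits for 18 kHz against 47 °C (real 21, highest other 2121) and 6 against 52 °C (123, 2437). For 1 kHz they came from 13 against 42 °C (58, 119), 10 against 47 °C (15, 159) and 6 against 52 °C (171, 327). A split can keep the real groups of either batch, and so its effect, so that these counts cannot decide on chance.

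The fall of immediate early genes at 18 kHz was weighed against 3 technical or physical explanations. Dim arrays alone are argued against, since under median scaling the list's median lay at -1.616, which is -0.505 beyond the -1.111 of random lists of like level in untreated cells, and 0 of 10000 random lists went as low. A beadchip effect is argued against by the median of -1.043 within the beadchip that holds both groups. Warming like that of the 42 °C group is argued against, since 5 of 7 heat shock genes that rose at 42 °C had a lower response at 18 kHz by the test of the difference, or 4 of 6 without Hspa4l, whose other probe did not rise at 42 °C, although Hspa1a and Hspa1b were at background in batch A. A change shared with the 47 and 52 °C groups stays open. Genes lower at 18 kHz and 47 °C were 9.9 times those of independent lists. Arrays of both were also dimmer than untreated ones, which was not tested as a cause. Handling of cells on the device, apart from the field, was not tested, but 1 kHz actuation shared that handling and left Fos at 11.82 ± 0.20.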

How the results depend on the processing

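The values without both 18 kHz or both 52 °C arrays that stand apart, the list shifts within beadchips, and the leave-one-out values of differences and correlations were chosen after the result was seen, and the other alternatives were planned. The 6 correlations between effects moved by less than their spread in each of 24 values under other settings. Values of named genes kept their direction and side of the threshold in 4601 planned cases without leave-one-out, while 324 newly passed it, 588 no longer passed it and 1 reversed (Ddit3, 1 kHz against 18 kHz, from -0.118 to 1.219 under median scaling, where all genes moved by a median of 1.129). The count of 0 genes at 1 kHz against untreated cells held under each alternative run. Of called genes with another measured probe, 17 of 69 had one called the same way at 18 kHz, 13 of 63 for 1 against 18 kHz, 25 of 75 at 42 °C, 78 of 252 at 47 °C, 146 of 464 at 52 °C, 16 of 71 for 47 against 42 °C and 34 of 130 for 52 against 47 °C, and 10 at 47 °C and 12 at 52 °C had one called the opposite way. The other counts moved by over 1.5 times as follows, and the cause was not tested.

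Genes for 18 kHz against untreated (246) and 1 kHz against 18 kHz (231) came to 801 and 707 without background correction, 4634 and 5108 under median scaling, 1623 and 1524 in the deposited log2 table, 513 and 463 with an offset of 50, 100 and 109 without the detection filter, 739 and 802 with detection in every array, 434 and 351 with all probes, 2115 and 1691 with array weights, 770 and 758 with a trended and robust prior, 28 and 24 from only the 2 groups, 1178 and 1094 with all 21 arrays together, 144 and 111 with a beadchip block, 128 and 129 with a replicate block, and 70 and 75 without both dimmer 18 kHz arrays, with 1 array left in that group. Within beadchip A2 they came to 2 and 0, and 1 kHz against 18 kHz to 2747 within beadchip A1. Nearly all median scaling calls point one way, and dim arrays were not told apart from a loss of transcripts.

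Genes at 42 °C (267) came to 464 in the deposited log2 table, 1297 with array weights, 492 from only the 2 groups, 410 with a beadchip block, and 17 and 15 within beadchips B1 and B2. Genes at 47 °C (791) came to 2809 under median scaling, 1314 in the deposited table, 480 without the detection filter, 1899 with array weights, and 481 and 0 within B1 and B2. Genes at 52 °C (1386) came to 2982 under median scaling, 2114 in the deposited table, 3557 with array weights, 559 from only the 2 groups, 888 and 6 within B1 and B2, and 130 without both 52 °C arrays that stand apart. Genes for 47 against 42 °C (265) came to 427 under median scaling, 442 in the deposited table, 840 with array weights, and 46 and 5 within B1 and B2. Genes for 52 against 47 °C (412) came to 110 under median scaling, 1053 in the deposited table, 252 without the detection filter, 1248 with array weights, 3 from only the 2 groups, 626 with all 21 arrays together, 755 with a beadchip block, 223 with a replicate block, 15 and 0 within B1 and B2, and 218 without both 52 °C arrays. Fits within a beadchip hold fewer arrays, down to 1 in a group, whose spread is then taken from the other groups.

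With an estimated correlation 1 list stayed shifted at 42 °C, 2 for 47 against 42 °C and 0 elsewhere. The 3 lists at 1 kHz became 0 by fry, 1 with a beadchip block and 6 within beadchip A2. The 5 lists for 52 against 47 °C became 8 without background correction, 8 in the deposited log2 table, 11 by fry and 9 within beadchip B1.

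Differences between effects also moved. In the deposited log2 table they came to 498, 340 and 612 genes for 18 kHz less 42, 47 and 52 °C (179, 21 and 123), and to 129, 141 and 542 for 1 kHz (58, 15 and 171). Without background correction those against 47 °C came to 115 for 18 kHz and 49 for 1 kHz, and with each batch normalized alone to 38 and 25. Without the detection filter those against 52 °C came to 57 and 111. With a beadchip block 18 kHz less 47 °C gave 39, 18 kHz less 52 °C gave 240 and 1 kHz less 52 °C gave 70.

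With 1 array left out, the genes changed ran from 27 to 2948 at 18 kHz, 0 to 0 at 1 kHz, 24 to 2557 for 1 against 18 kHz, 133 to 179 at 42 °C, 218 to 431 at 47 °C, 424 to 2801 at 52 °C, 105 to 239 for 47 against 42 °C and 42 to 1238 for 52 against 47 °C. The highest counts came without 18 kHz replicate 3 or 52 °C replicate 1, which left the pair of arrays that stand apart in each group. Besides those in the report, medians of shifted lists moved most for immediate early genes at 1 kHz (-0.277 to -0.112), unfolded protein response genes at 18 kHz (-0.403 to -0.163), histone genes at 1 kHz (0.102 to 0.262), NF-kB targets at 52 °C (-0.562 to -0.252) and splicing regulators for 47 against 42 °C (-0.269 to -0.097). Shifted lists numbered from 2 to 6, 1 to 5, 2 to 5, 5 to 9, 8 to 12, 7 to 11, 5 to 7 and 5 to 10 in the same order. Differences from 42, 47 and 52 °C ran from 97 to 1100, 17 to 703 and 30 to 1080 at 18 kHz, and from 37 to 54, 9 to 14 and 53 to 1076 at 1 kHz. Correlations with the 42, 47 and 52 °C effects ran from 0.226 to 0.315, 0.446 to 0.508 and 0.368 to 0.463 at 18 kHz, and from 0.106 to 0.208, 0.061 to 0.203 and 0.128 to 0.235 at 1 kHz.

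The replicate numbers do not pair the samples. Across genes, deviations of same-number arrays correlated at -0.243 to 0.475 in batch A, with 3 of 9 pairs over 0.1, and at -0.421 to 0.154 in batch B, with 5 of 18 over 0.1, while arrays of different numbers reached 0.451 and 0.508. The replicate block is therefore given only as an alternative. Signal over background limits the data where a gene lies at background on all arrays of a group, as Hspa1a and Hspa1b did on all 9 of batch A and Atf3 on all 21.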

Other observations

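All tests of explanations in this part were chosen after the result was seen.

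A set of 11 genes, chosen after their values were seen, was lower at 18 kHz and in each heat group: Fos, Fosb, Dusp2, Osm, Ier3, Csrnp1, Zfp36, Ccl3, Mir17hg, Srsf6 and Slc30a1, a zinc exporter gene, passed in all 4 comparisons with untreated cells, and 0 of them at 1 kHz. At 42 °C Zfp36 (adjusted p = 0.0445), Csrnp1 (adjusted p = 0.0357) and Ccl3 (adjusted p = 0.0346, lost without any 1 of the 6 arrays, up to 0.134) were near the threshold, as were Slc30a1 (adjusted p = 0.0483) and Srsf6 (adjusted p = 0.0351, up to 0.158 without any untreated array or 18 kHz replicate 1 or 2) at 18 kHz. At 42 °C Jun and Egr1 rose while Fosb and Fos fell, so that subunits of AP-1 moved in opposite directions. The list of genes downstream of interleukin 3 and STAT5 passed its test at 42 °C (-0.37, but adjusted p = 0.0803 with an estimated correlation) and not at 47 °C (-0.13, adjusted p = 0.0926) or 52 °C (-0.13, adjusted p = 0.186), and its difference between 47 and 42 °C did not pass (0.16, adjusted p = 0.119). At 47 °C histone transcripts, most of which end without a poly(A) tail, lay higher (0.42, adjusted p = 0.363 with an estimated correlation, and -0.04 under median scaling, or 0.39 relative to the shift of all genes), and Rpph1, another RNA without such a tail, rose at least 2.26-fold.

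Other splits of the 6 arrays of a comparison number 10 with the real one, too few for a share below 0.05. The splits that gave as many genes, the real one included, numbered 1 at 18 kHz (real 246, highest other 0), 10 at 1 kHz (0, 0), 2 for 1 against 18 kHz (231, 366), 1 at 42 °C (267, 0), 1 at 47 °C (791, 52), 1 at 52 °C (1386, 0), 1 for 47 against 42 °C (265, 0) and 1 for 52 against 47 °C (412, 2). The split with 366 genes set beadchip A1 against beadchip A2. For lists the splits numbered 1 (6, 4), 3 (3, 7), 1 (4, 2), 1 (6, 4), 1 (10, 8), 2 (9, 10), 3 (5, 5) and 3 (5, 7) in the same order.

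Shared untreated groups raise the likeness of effects within a batch. Effects at 18 and 1 kHz correlated across genes at 0.261, against 0.499 in 100 simulations with shared untreated arrays and no effects. Those of 42 and 47 °C correlated at 0.554, of 47 and 52 °C at 0.61 and of 42 and 52 °C at 0.456, against 0.5, with covariances of 0.0809, 0.1143 and 0.0774 against 0.0206. In the same order 63, 160 and 64 genes were lower in both, where independent lists, without regard to the shared arrays, give 5.06, 22.13 and 7.98.

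Some large rises at 42 °C rested on 1 probe, that of the heat shock gene Hspa4l among them (2.66, its other probe at -0.07), and 2 explanations were weighed. For a rise of the whole transcript, the other probes of the 37 called genes that have any rose by a median of 0.304 where the called ones rose by 0.911, a ratio of 0.334, against 0.818 for 38 falling genes. For one signal read by all these probes, such as a common sequence, the deviations of 10 of the 14 probes correlated at 0.236 in batch A, where random sets stayed below 0.192 in 95% of draws and 25 of 1000 went as high. Neither test decides, since the ratio lay between the values set for and against a whole transcript and the correlation, though above that of most random sets, was low. The rises of the receptor gene Ifngr2 (3.27, its 2 other probes at 0.02 and 0.30) and Arnt (2.71) may thus be of a transcript form or of the probe.

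Granule genes set the heat groups apart, and a culture of another state among the arrays is a candidate explanation. At 52 °C Mcpt8 stood at 11.09, 8.69 and 8.54 and Hdc at 10.06, 7.79 and 7.93 in replicates 1, 2 and 3. Prtn3 (7.06, 8.58, 8.51), Fcgr3, Adgre1 and Fcer1a went the other way. The hemoglobin gene Hba-a1 stood at 9.95 and 9.9 in replicates 2 and 3, against 4.53 to 5.38 on the other arrays of batch B. It stood at 8.51 to 9.86 in batch A. The difference of replicates 2 and 3 from replicate 1 correlated across genes with that of untreated batch A from untreated batch B at 0.405, where arrays of the other groups of batch B, each set against the others of its group, gave -0.15 to 0.107. A beadchip effect is argued against, as the mast cell list was lower at 52 °C on both beadchips (-2.141 and -1.665). Other cells in some cultures cannot be told from a change within the cells: 7 of 10 myeloid genes were lower at 42 °C, 2 of them called, and untreated cells of batch B had 9 of the 10 detected on all 3 arrays, with S100a8 at 11.02 and Ctsg at 10.99. The labels name no difference between these replicates. Unlike the Hba-a1 difference within batch B, the correlation of 0.405 and the batch A levels rest on separately normalized batches. The explanation stays open.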
